A study of Drosophila melanogaster with 4 samples.

How the data were processed

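The data were lists of enriched regions from ChIP-seq for CTCF in Oregon-R embryos of 14 to 16 h. Per the labels' protocols, embryos were crosslinked with 1.8% formaldehyde and chromatin was incubated with antibody for 15 h. The libraries were grouped from the labels into 2 CTCF ChIP libraries and 2 input libraries, each input serving 1 ChIP library per the labels. The labels do not say that the replicates came from separate collections, so differences between them may be technical. All p-values are taken over the regions of these lists and measure no spread between libraries. The input libraries were not analysed here.

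The authors deposited 3 region lists, 1 per ChIP library and 1 for both together, in FlyBase release 5 coordinates per the file headers. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The peak caller, its threshold, the use of the input and the way both libraries were combined are not given in the sources used here. Each region in the deposited lists carries a score, and the formula of that score is not stated in the files. The score is the authors' own value for each region and was used to describe, rank or filter regions within a list. Score values themselves entered Pearson's r over shared regions, the differences between X and autosome scores in the pooled list, and the span of scores in a run of regions. Distinct scores with another exactly 1 higher (tolerance 1e-08) numbered 23, 20 and 42 in the replicate 1, replicate 2 and pooled lists, and those with another 1.58 higher (log2 of 3) numbered 8, 7 and 20. None had a partner 0.9, 1.1 or 0.693 (natural log of 2) higher, and 1, in the pooled list, had one 0.301 (log10 of 2) higher, a pattern that a log2 scale of read ratios would give. The scale is otherwise not known, and no fold enrichment was derived from it. Positions were kept as listed, counted from 1.

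The pooled list held 1 region marked as depleted, at 2R 15415684 to 15417170 with a score of -0.011, which was left out, leaving 3888 regions. Sequence lengths came from the file headers, for 14 sequences of 168.7 Mb in all. Read depth is unknown, so no value has an error from sequencing depth. Wilson and exact binomial intervals at 95% cover counting only and treat regions as independent. For sequences with no region the limit from 0 is 3 regions, which does not apply below the authors' threshold.

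A region was shared when it overlapped a region of the other list by at least 1 bp. Chance overlap came from 100000 circular shifts of 1 list within each sequence, with a two-sided p that cannot be below 2e-05. The shifts also moved regions into sequence that may not be mappable, which lowers the chance level. Score order was compared by Spearman's rho and Pearson's r over shared regions, taking the highest-scoring partner, with 100000 resamples. Score percentiles of shared and unshared regions were compared by the difference of medians with a permutation test of 100000 resamples. Density was compared by an exact binomial test of region number against sequence length, on the 5 arms 2L, 2R, 3L, 3R and X. Families of tests were adjusted by the Benjamini-Hochberg method and judged at 0.05.

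Regions were named by a rule with these parts: the 15 pooled regions with the highest score, the 5 highest-scoring unshared regions of each replicate, and the 3 windows of 100 kb with most pooled regions. Other parts of the rule named regions near homeotic and insulator protein genes and genes of passing lists. These, and tests of 14 gene lists, of transcription start sites and of 7 sequence motifs, need a genome or annotation of release 5, which was not used here, and were not run. These comparisons, rules and most alternative settings were fixed before the data were examined. The score deciles and quintiles, the densities of sequences other than X, the XHet run and the tests on windows were added afterwards.

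Alternatives were a reciprocal overlap of 50%, centres within 200 bp, the higher-scoring part of each list above its median, each replicate alone, regions of both replicates, and covered bases in place of region number. Alternatives with 10000 shifts cannot give a p below 2e-04. The code was tested on simulated data. A planted overlap of 70.8% with the 2408 replicate 1 regions was recovered as 71.6%, 4% of 200 independent random lists had a p under 0.05, and a planted X density ratio of 1.5 was recovered as 1.43 from 3700 regions. The software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.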

Results

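Chromatin bound by CTCF was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of the wild-type Oregon-R strain, collected at 14 to 16 h of development. CTCF is a zinc-finger DNA-binding protein of chromatin insulators, the elements that limit contact between enhancers and promoters. There were 2 CTCF ChIP libraries (replicates 1 and 2) and 2 input libraries, which are sheared chromatin sequenced without immunoprecipitation. Each ChIP library gave 1 list of enriched regions, and the authors deposited a further list for both libraries together, called the pooled list here. No values of the input libraries were analysed here, and read totals are unknown, so the depth behind each list cannot be given. All positions are in FlyBase release 5, and no annotation of that release was used, so regions are given by position without a gene.

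CTCF-enriched regions covered a small part of the genome, spread over every chromosome arm. The replicate 1 list held 2408 enriched regions over 5.22 Mb, or 3.09% of the assembly, and the replicate 2 list held 2080 regions over 4.59 Mb, or 2.72%. The pooled list held 3888 regions over 7.69 Mb, or 4.56%. Median region widths were 2106 bp in replicate 1, 2188 bp in replicate 2 and 1939 bp in the pooled list. The shortest region was 1301 bp in each replicate list and 1001 bp in the pooled list, so the pooled list admitted shorter regions. The authors' score had a median of 0.68 in replicate 1 (range 0.15 to 6.0), 0.83 in replicate 2 (0.16 to 5.4) and 0.41 in the pooled list (0.063 to 5.7). With 1 list per library, these totals have no error.

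The strongest CTCF regions lay on all of the large arms and were strong in both libraries. Among the 15 pooled regions with the highest scores, 4 were on X, 4 on 2R, 3 on 3L, 2 on 2L and 2 on 3R. All 15 overlapped a region of each replicate, ranked no lower than 18 of 2408 in replicate 1 and 19 of 2080 in replicate 2. They were picked by the score of the pooled list, which was made from the same libraries, so these ranks are not independent evidence of agreement. The highest pooled score, 5.7, was at X 20630270 to 20632952, the strongest region of replicate 1 and number 2 of replicate 2. It was followed by 2R 16770798 to 16773722, which also scored 5.7 and held ranks 2 and 1. Next were 3R 10215524 to 10218530 with a score of 5.3, X 17424484 to 17428126 with 5.3, and 3R 3633782 to 3637484 with 5.2. The regions at 2L 20119634 to 20122692 and 2R 4137932 to 4140538 each scored 5.2, and 3L 3615168 to 3618158 scored 5.1. Further regions with a score of 5.1 were 2R 2036498 to 2040890, which ranked 3 in replicate 1 and 17 in replicate 2, and 3L 504516 to 509238. The remaining members were 2L 14704398 to 14707750, 3L 2850346 to 2853722, 2R 11224494 to 11229188, X 1845456 to 1848624 and X 9671456 to 9673986, with scores from 4.97 to 5.03. These 15 regions were 2531 to 4723 bp wide, wider than the pooled median of 1939 bp.

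The first comparison asked how far both libraries recovered the same CTCF regions. Of the 2408 replicate 1 regions, 1830 overlapped a replicate 2 region by at least 1 bp, or 76.0% (95% Wilson interval 74.3 to 77.7). In the other direction, 1836 of 2080 replicate 2 regions overlapped replicate 1, or 88.3% (86.8 to 89.6). Both shares were 10.4-fold above the mean after one list was shifted around its sequences, which was 7.34% for replicate 1 and 8.47% for replicate 2. None of 100000 shifts gave a share as high as the observed one. The highest shifted share was 23.2% for replicate 1 and 27.0% for replicate 2, and the two-sided permutation p was 2e-05 in each direction, the smallest that the shifts can give.

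Overlap rose with region score in both lists. In the lowest score decile of replicate 1, 122 of 241 regions (50.6%) were shared, and in the next decile 41.1%. The shared portion passed 90% in decile 6 (90.5%) and reached 241 of 241 and 240 of 240 regions in the highest pair of deciles. In replicate 2, 142 of 208 regions (68.3%) were shared in the lowest decile and 207 of 208 (99.5%) in the highest. Shared regions of replicate 1 had a median score percentile of 61.6, against 22.1 for the 578 unshared ones, a gap of 39.5 points. In replicate 2 the medians were 55.6 for shared regions and 18.6 for the 244 unshared regions, a gap of 36.9 points. Each gap had a permutation p of 1e-05 (two-sided, 100000 resamples, Benjamini-Hochberg adjusted 1e-05 over 2 tests), the smallest that the resamples can give.

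**Figure D1:**
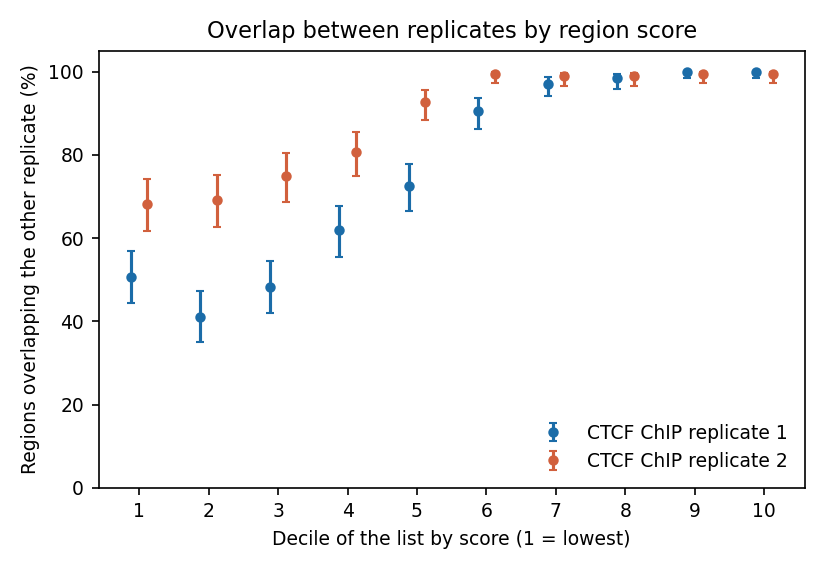
Percent of regions that overlap a region of the other replicate (y axis) by decile of the list ranked by the authors' score (x axis, 1 is lowest), for CTCF ChIP replicate 1 (blue) and replicate 2 (orange). Points are shares with 95% Wilson intervals, and they rise from 50.6% and 68.3% in the lowest decile to 100% and 99.5% in the highest.

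Regions found in both libraries mostly kept their order of strength, with more scatter among the weaker regions. Across the 1830 shared regions, Spearman's rho between the scores in both replicates was 0.938 and Pearson's r was 0.981. The permutation p was 1e-05 for each, the smallest that 100000 resamples can give, and the adjusted value over these 2 relations was 1e-05. The median difference in score percentile was 4.87 points, and in 31 of 1830 pairs it was over 40 points. These correlations are across regions, which are not independent replicates.

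**Figure D2:**
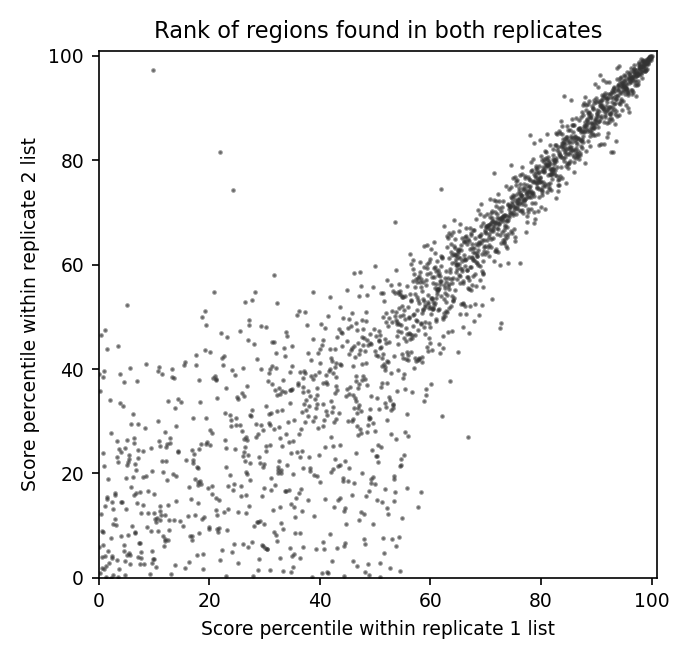
Score percentile of each of the 1830 regions found in both replicates, within the replicate 1 list (x axis) and within the replicate 2 list (y axis). Each point is 1 region, and the points lie close to a line at high percentiles and scatter at low ones (Spearman's rho 0.938).

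Unshared regions were mostly weak and, like most regions of each list, mostly on the chromosome arms. The highest-scoring few lay outside the arms. U is the set of unplaced scaffolds. Of the 578 unshared regions of replicate 1, 563 were on the arms or chromosome 4, and 34 scored above the list's median, 23 of them on the arms or chromosome 4 and 11 on U or heterochromatin. Of the 244 unshared regions of replicate 2, 233 were on the arms or chromosome 4 and 11 on U or heterochromatin. The whole list of 2080 regions had 2024 on the 5 large arms and 14 on chromosome 4. It had 17 on U, 10 on XHet and 15 on chromosome 2 and 3 heterochromatin, again more often unshared than regions on the arms. Only 7 of the 244 scored above the median, and all 7 were on U or heterochromatin. The 5 strongest unshared regions of each replicate were likewise all on U or heterochromatin. For replicate 1 these were U 6057340 to 6058722 with a score of 2.1, U 903023 to 904406 with 2.0, U 1713103 to 1714439 with 1.6, U 2499173 to 2500484 with 1.6, and 3LHet 1238975 to 1240947 with 1.5. For replicate 2 they were U 9159860 to 9161266 with 3.9, 2LHet 326804 to 328315 with 3.0, U 7084777 to 7086749 with 2.0, U 9288003 to 9289338 with 2.0, and U 9407510 to 9409487 with 1.8. The region at U 9159860 ranked 129 of 2080. It overlapped no pooled region, and neither did the replicate 1 regions at U 903023, U 1713103 and U 2499173.

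The second comparison set the pooled list against each library. The pooled list contained nearly all regions of either replicate, with 2372 of 2408 replicate 1 regions (98.5%) and 2058 of 2080 replicate 2 regions (98.9%) overlapped by a pooled region. Of the 3888 pooled regions, 1814 (46.7%, Wilson 45.1 to 48.2) overlapped regions of both replicates, 7.66-fold above the shifted mean of 6.09% (two-sided permutation p = 2e-05, the smallest that 100000 shifts can give). A further 539 (13.9%) overlapped replicate 1 alone and 225 (5.79%) replicate 2 alone. The other 1310 pooled regions (33.7%) overlapped neither list. Pooled regions seen in both replicates were the stronger and wider ones, with a median score of 1.0 and a median width of 2347 bp. Those seen in neither had a median score of 0.35 and a median width of 1232 bp, and 750 of the 1310 (57.3%) were shorter than the 1301 bp minimum of the replicate lists. Among pooled regions of at least that length, 1814 of 3062 (59.2%) were seen in both replicates. The pooled list was made from the same libraries, so its overlap with them is not independent evidence.

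Regions seen in neither replicate were unevenly spread over the genome. They made up 1214 of 3724 pooled regions (32.6%) on the 5 large arms, 65 of 90 (72.2%, Wilson 62.2 to 80.4) on U, and 24 of 41 (58.5%, 43.4 to 72.2) on chromosome 2 and 3 heterochromatin. On U their median score was 1.4, and on the large arms it was 0.34. Of the 91 such regions with a score over 1, 64 were on U or heterochromatin and 27 on the large arms.

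The third comparison asked whether CTCF regions were spread evenly over the chromosome arms. The X chromosome carried more regions per Mb than any autosome arm in all 3 lists. The pooled list had 37.8 regions per Mb on X (847 regions), against 33.6 on 2R, 30.9 on 3R, 27.4 on 2L and 27.4 on 3L. The density ratio of X to the 4 autosome arms was 1.27 (exact 95% interval 1.17 to 1.37, two-sided exact binomial p = 2.57e-09). It was 1.30 (1.18 to 1.43) in replicate 1, with 543 regions on X, and 1.27 (1.14 to 1.41) in replicate 2, with 460. Regions covered 7.60% of X and 5.92% of the autosome arms. Among the pooled regions with a score over 2 the ratio was 1.13 (0.920 to 1.39, exact binomial p = 0.224), so an excess was not detectable among the strongest regions.

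The X excess of the pooled list was largest at intermediate scores, and X had fewer regions than the autosome arms at the lowest scores. When the pooled regions were divided into quintiles by score, the density ratio was 0.433 in the lowest (exact 95% interval 0.332 to 0.556, adjusted exact binomial p = 1.03e-12) and 0.997 in the next (adjusted p = 1). It was 1.99 in the middle quintile (1.69 to 2.32, adjusted exact p = 8.44e-16), 2.00 in the one above (1.70 to 2.34, adjusted p = 7.74e-16) and 1.26 in the highest (1.05 to 1.49, adjusted p = 0.0141). The ratio in the lowest quintile was also below 1 in replicate 1, at 0.607 (0.453 to 0.800), and in replicate 2, at 0.663 (0.488 to 0.885). The next quintile, near 1 in the pooled list, had a ratio of 1.37 in replicate 1 (adjusted exact p = 0.00619) and 1.69 in replicate 2 (adjusted p = 1.69e-05), the largest ratio of that list. In the highest quintile neither replicate alone passed 0.05, with adjusted exact p-values of 0.201 and 0.477. The p-values are adjusted over 15 tests, 5 quintiles in each of 3 lists.

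**Figure D3:**
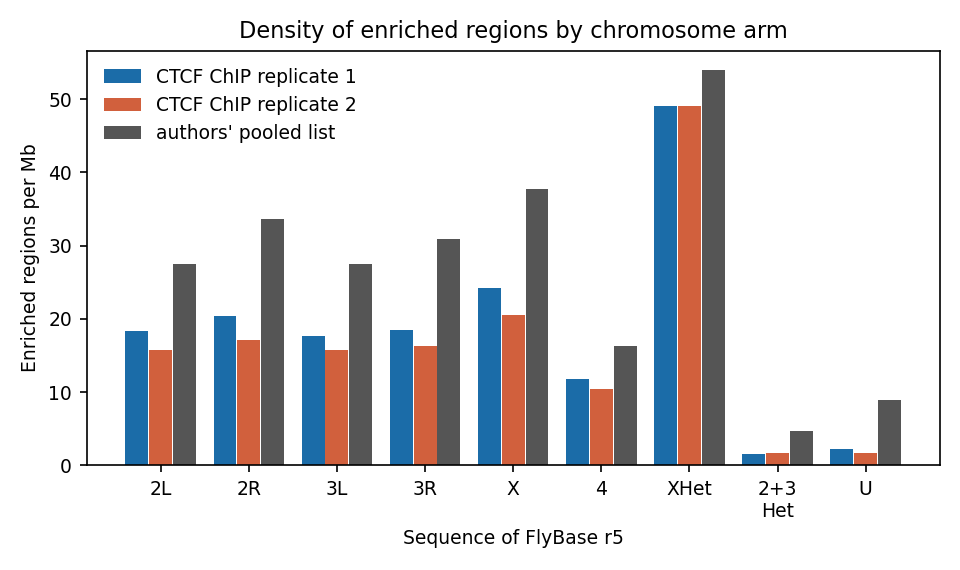
Enriched regions per Mb (y axis) on each sequence of FlyBase release 5 (x axis), for CTCF ChIP replicate 1 (blue), replicate 2 (orange) and the authors' pooled list (grey). Bars are single values without error, and X stands at 24.2, 20.5 and 37.8 regions per Mb, above each autosome arm in the same list.

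Other sequences departed from the autosome arms as well. Chromosome 4, a small and largely heterochromatic chromosome, had 22 pooled regions and a density ratio of 0.546 (adjusted exact binomial p = 0.00405). Its ratio was 0.634 in replicate 1 (adjusted exact p = 0.0805) and 0.640 in replicate 2 (adjusted p = 0.112), so neither replicate alone passed 0.05. Arm 2R had 1.17 times the density of the other autosome arms in the pooled list (adjusted exact p = 6.59e-04) and 1.12 times in replicate 1 (adjusted p = 0.0478), and its ratio of 1.07 in replicate 2 did not pass (adjusted p = 0.233). Arm 2R was the densest autosome arm in each list, and 2L, 3L and 3R were not tested in this way. The adjustment does not cover that choice of arm. Heterochromatin of chromosomes 2 and 3 was poor in regions, with 4.70 per Mb and a ratio of 0.158 (adjusted exact p = 2.97e-59), and U had a ratio of 0.301 (adjusted p = 5.68e-42). The ratios were lower in the replicate lists, at 0.0798 and 0.106 for this heterochromatin and 0.123 and 0.104 for U in replicates 1 and 2. No list held a region on YHet, from the Y chromosome, or on Uextra, a further set of unplaced sequence. These p-values are adjusted over 15 tests, and how much of each repeat-rich sequence could be mapped is unknown.

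XHet, the short heterochromatin sequence of X, was the exception among heterochromatin sequences. It held 10 regions in replicate 1, 10 in replicate 2 and 11 in the pooled list, or 49.0, 49.0 and 53.9 per Mb. The density ratio to the autosome arms was 2.63 in replicate 1 (adjusted exact p = 0.00896) and 3.03 in replicate 2 (adjusted p = 0.00405), and 1.81 in the pooled list (adjusted p = 0.0778). The exact test treats regions as independent, whereas 7 regions of each list belong to the evenly spaced run described next. These ratios and p-values therefore rest largely on that run. Within XHet, 7 consecutive pooled regions from 89564 to 127202 were evenly spaced, with centres 5895 ± 43.2 bp apart (SD over 6 gaps). The same run was spaced 5893 ± 53.9 bp in replicate 1 and 5902 ± 50.1 bp in replicate 2. Scores in the run were 0.98 to 1.3 in the pooled list, 0.98 to 1.3 in replicate 1 and 0.92 to 1.5 in replicate 2. This run was singled out after its values were seen.

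**Figure D4:**
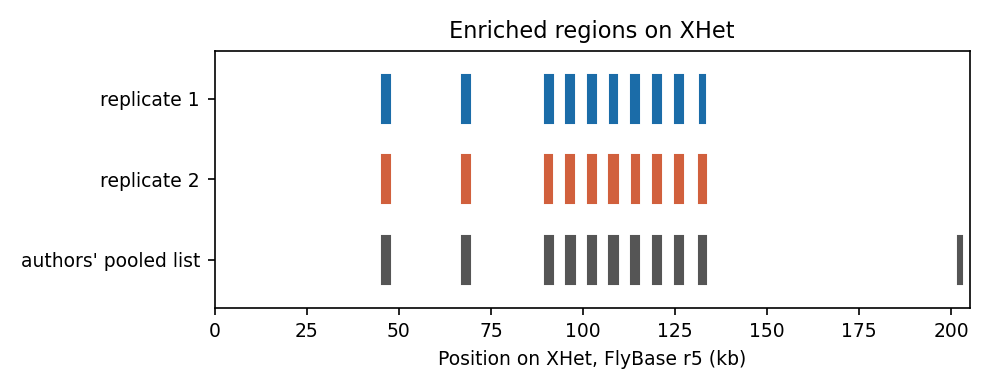
Positions of enriched regions along XHet in FlyBase release 5 (x axis, kb) for CTCF ChIP replicate 1 (blue), replicate 2 (orange) and the authors' pooled list (grey), drawn to scale. Each bar is 1 region, and 7 regions from 89564 to 127202 bp in the pooled list are spaced 5895 bp apart on average.

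Clustering of regions along the arms was described in 100 kb windows. The window with most pooled regions was 3R 12000001 to 12100000, with 14 regions, of which 8 were seen in both replicates. It was followed by X 1200001 to 1300000 with 11 regions, 6 of them in both replicates, and 2R 5400001 to 5500000 with 10, 5 of them in both. Random placement of the same number of regions on each arm gave a densest window of 11 regions at the median, and 14 or more with a one-sided permutation p of 0.0122 over 10000 simulations. The same window was the densest in replicate 2 alone, with 10 regions (permutation p = 0.0196), and in replicate 1 alone, with 9 (p = 0.290). With windows moved by 50 kb the densest was another one, 3L 17550001 to 17650000 with 10 regions (permutation p = 0.910), so the excess depended on where windows began. Windows without any pooled region numbered 100 of 1194, against 58 at the median of the simulations (one-sided permutation p = 1e-04, the smallest that 10000 simulations can give). Random placement took no account of broad sparse parts of an arm, such as those nearest most centromeres, or of sequence that may not be mappable. The number of empty windows therefore does not by itself show local clustering.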

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

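Of the tests below, the resampling of blocks over all pooled regions and the comparison of short with long regions were planned before their results were seen, and the others were chosen after. The design has a single genotype and stage, so no biological explanation was tested for any pattern.

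CTCF regions were listed on sequences outside the arm comparison: 90 pooled regions on U, 11 on XHet and 41 on chromosome 2 and 3 heterochromatin. Their density ratio to the autosome arms was 0.301 on U, 0.158 on chromosome 2 and 3 heterochromatin and 1.81 on XHet. Neither replicate list matched 65 of the regions on U, 24 of those on this heterochromatin and 1 on XHet.

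The pooled list had 1.27 times as many regions per Mb on X as on the autosome arms. Uneven local density along the arms is argued against, since resampling 1 Mb blocks gave a lower 95% bound of 1.15 (upper 1.41). A constant upward shift of X scores by the 0.060 gap between the 5th percentiles would give a ratio of 1.04 at scores over 1, and by the 0.078 gap between the medians 1.05, both below the lower bound of 1.08 from resampled blocks (observed ratio 1.25). These gaps are measured only on listed regions, so a larger shift stays open, and the ratio of 0.433 in the lowest score quintile goes with a shift. Read coverage of X and autosomes was not measured, so whether a difference in it would raise or lower the ratio is unknown. The ratio of 1.13 at scores over 2 cannot decide, because its interval of 0.920 to 1.39 includes both 1 and 1.27. Nor does the ratio of 0.433 in the lowest quintile tell a shift of scores from a difference in coverage.

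A group of 1310 pooled regions overlapped neither replicate list. A shorter minimum length in the pooled list is a candidate explanation for the short ones. Regions under 1301 bp exceeded longer regions of the same score quintile in their unmatched share by at least 34.0 percentage points. Short regions of the same score may also rest on fewer reads, so this comparison cannot separate the minimum length from scores made from few reads. Of the unmatched regions, 42.7% (Wilson 40.1 to 45.4) reached that length in the pooled list. Their length in each library alone is unknown, so whether the minimum length accounts for these longer ones cannot be told. Scores made from few reads are consistent with the values, as 27.6% of unmatched regions had a score that occurs again exactly, against 4.24% of regions matched in both replicates (odds ratio 8.58, Fisher's exact p = 2.13e-78) and 16.0% of those matched in 1 replicate, whose median score of 0.31 was closer to the 0.35 of the unmatched (odds ratio 2.00, p = 9.98e-10). Weak regions that pass only with the reads of both libraries combined stay open, since read totals are unknown.

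The evenly spaced run of 7 regions in XHet may reflect tandem copies of one sequence. Chance spacing is argued against, as the most even run of 7 pooled regions on any other sequence had a relative spread of gaps 23.7 times as large (17.4% against 0.733%, 3820 runs in all), with 13.1 times in replicate 1 and 24.4 times in replicate 2. Copies of one sequence would also tend to score alike. Of 3815 pooled runs on other sequences, 7.10% had scores spanning no more than the 0.32 of this run, which leaves tandem copies open. In replicate 2 the scores of the run spread more widely, from 0.92 to 1.5. No sequence was used here, and how reads matching several places were treated is not given in the sources used here.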

How the results depend on the processing

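Restriction to the large arms, to longer pooled regions or by score over 1 or 2, and every alternative for the densest window, were chosen after seeing the data. Of 31 alternatives over 8 results, 28 were counted as unchanged. For most, this meant the same direction and the same side of the threshold. The X ratio from covered bases (1.28) had no test and was counted because it lay within the interval of the main ratio. For the densest window, unchanged meant only a count within 1.5 times. Windows moved by 50 kb were so counted, although another window was then densest and the result was not past the threshold. The share of replicate 1 regions in replicate 2 ranged from 66.1% to 84.1%, that of replicate 2 in replicate 1 from 76.5% to 97.0%, and that of pooled regions in both from 40.1% to 59.2%. The 84.1% and 97.0% compared only the higher-scoring parts of both lists, so they are not shares found in the full other list. The 59.2% took only the longer pooled regions. The X to autosome ratio ranged from 1.13 to 1.77, highest in the higher-scoring part of the pooled list, and leaving out a replicate gave 1.27 to 1.30. At scores over 2 it was 1.13 (0.920 to 1.39), no longer past the threshold, and the cause was not tested. The densest window, with 14 regions, stayed in place and past the threshold in replicate 2 alone (10 regions, permutation p = 0.0196). It was in place but not past it in replicate 1 alone (9, permutation p = 0.290) and in the higher-scoring part of the pooled list (8, p = 0.502), and with windows moved by 50 kb another window was densest (10, p = 0.910). No paired analysis was possible because the input libraries have no values here and only the ChIP libraries have region lists. The tests on start sites, motifs and gene lists, and an alternative score column, which the lists do not have, were not run. Read depth is unknown, so its effect on the weak regions could not be measured.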

Other observations

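The tests in this part were all chosen after the data were seen. CTCF regions were sparse in the 10% of most arms nearest the centromere, where an even spread would place 10% of an arm's regions. In the pooled list, 21 of 711 regions on 2R (2.95%, adjusted exact binomial p = 1.19e-11), 39 of 673 on 3L (5.79%, adjusted p = 5.26e-04), 45 of 631 on 2L (7.13%, adjusted p = 0.0211) and 61 of 847 on X (7.20%, adjusted p = 0.00980) lay in that part. Arm 3R held 103 of 862 regions there, or 11.9%, which did not differ from an even spread by the test (adjusted exact p = 0.0760). The shortfall on 2R was also present in replicate 1 (2.31%) and replicate 2 (1.93%), and on X it did not pass in replicate 1 (7.37%, adjusted exact p = 0.0610) or replicate 2 (7.83%, adjusted p = 0.160). The values are adjusted over 15 tests and treat regions as independent. The even spread was taken over sequence length, and how much of these parts could be mapped is unknown. A shortfall of listed regions there need not be a shortfall of CTCF binding.

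The single pooled region of XHet that neither replicate listed, at 201764 to 202770, scored 3.2 over 1007 bp, the highest score on that sequence. Of the 91 pooled regions with a score over 1 that neither replicate listed, 67 (73.6%) had a score that occurs again exactly in the list, and their median width was 1019 bp.

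The strongest unshared region on the arms was X 21791081 to 21793150 in replicate 1, with a score of 1.4 and rank 769 of 2408, and X 19921700 to 19923016 in replicate 2, with a score of 0.76 and rank 1091 of 2080. The 1 depleted region of the pooled list overlapped 1 enriched region of replicate 2 and none of replicate 1.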
